A study of Escherichia coli with 2 samples.

How the data were processed

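Transcripts of Escherichia coli strain B178 with its own groES and groEL deleted were measured on 2 Affymetrix antisense genome arrays, 1 per group. In both groups a first plasmid carried wild type human Hsp60, the mitochondrial chaperonin, with its co-chaperonin Hsp10 under an IPTG-inducible promoter. A second plasmid carried an arabinose-inducible operon with Hsp10 and either wild type Hsp60 or the Val98Ile mutant. Per the labels' protocols, cultures grew at 30 °C with 0.1 mM IPTG to an optical density of about 0.1, were moved to fresh medium with 0.2% arabinose, and were sampled after 10 h. RNA of 2 wild type transformants and of 3 mutant transformants was pooled before labelling, so each group is 1 array and no replicate error can be estimated.

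The deposited values are signal intensities on a linear scale, 1 per probe set, made with MAS5 per the submitters' processing notes. Its version and settings are not given in the sources used here. In the deposited table the mean intensity after removing the lowest and highest 2% of probe sets was 150.1 on each array, so the authors' values had been scaled to a common level. MAS5 summarises each probe set from perfect-match and mismatch probes, which makes dim values noisy. Detection calls were not used here.

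Of 7312 probe sets, 4345 are named by locus, 2886 are intergenic, 59 are of phage or plasmid sequences and 22 are Affymetrix controls. The platform annotation lists 4398 of them, 3804 with 1 gene symbol and 594 with several different symbols; 2914 are not listed. Names were taken not from these symbols but from the K-12 MG1655 reference assembly ASM584v2. An Entrez identifier gave exactly 1 gene for 4286 probe sets, a locus tag in the probe set's name for 40 more, 42 matched several genes and were left unnamed, and 2944 matched none. No coordinates are given, because the genome build behind the array is not given in the sources used here. This left 4225 genes, 78 of them with several probe sets, of which the one with the highest mean log2 signal was used.

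Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6; figures were drawn with matplotlib 3.10.9. The mutant signals were multiplied by 1.06, which set to 0 the median log2 difference over probe sets brighter than the median of their array on both arrays (it was -0.087 as deposited). Signals under a floor of 41.5, the higher of the 2 scaled array medians, were raised to it, so that a gene above the floor on 1 array only gives a lower bound of its fold difference. A gene was counted as measured when it was above the floor on at least 1 array. Differences are log2 signals, mutant minus wild type. No test between groups was made and no p-value is given; a 2-fold difference is a rule of size.

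A total of 28 gene lists were fixed from general knowledge before the data were examined, as were the floor, the rules for named genes and the first 11 alternative settings. The lists are the deleted chaperonin genes, heat shock, other chaperones, chaperonin substrates, sigma E, Cpx, phage shock, general stress (RpoS), acid resistance, arabinose, lactose, carbon catabolism, flagella and chemotaxis, type 1 fimbriae, curli, colanic acid, ribosomal proteins, ATP synthase and aerobic respiration, the TCA cycle, anaerobic respiration and fermentation, SOS, oxidative stress, iron acquisition, methionine, cysteine and sulfate, amino acids, purines and pyrimidines, and cold shock. For each list with at least 3 measured genes, the median difference was ranked among the medians of 10000 random lists of the same size drawn from the measured genes outside it, matched on mean signal in 10 bins. This rank describes these 2 arrays only, and it treats genes as independent although neighbouring genes differed together. Named genes are the 12 highest and 12 lowest differences among genes above the floor on both arrays, the 5 highest and 5 lowest bounds among genes above it on 1 array, up to 2 highest and 2 lowest members of each list, and the chaperonin, arabinose and heat shock genes chosen in advance. Further members of lists are named where a list is described in full; those were chosen after their values were seen.

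The procedure was tested on simulated data for this comparison with 4225 genes and a noise SD of 0.3 on the log2 scale. It recovered 92 of 100 genes set 1.5 log2 units apart and 100 of 100 set 2.5 apart, and counted 2 unchanged genes as 2-fold different. The simulated noise was independent between probe sets and equal at all signals, and the changed genes were above the floor on both arrays. These numbers thus check the procedure and do not give the error of the real 2-fold differences, since dim MAS5 values are noisier. Of 200 unchanged lists of genes, 6 fell outside the middle 95% of random lists. The spread between different probe sets of the same gene, over 28 genes with 59 probe sets above the floor on both arrays, had a pooled SD of 0.31 on the log2 scale. It covers probe effects within the arrays, not differences between cultures, pools or hybridisations. The control probe sets were too dim to serve: 0 of 22 were above the floor on both arrays. The number of arrays limits the precision of every value.

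The 11 alternative settings were no centring, quantile normalization, loess (span 0.4), floors at the 25th or 75th percentile or at the 95th percentile of foreign (phage, F plasmid and non-E. coli control) probe sets, no floor, a pseudocount equal to the floor, the mean over a gene's probe sets, leaving out _s_at and _x_at probe sets, and unmatched random lists. Another 3 settings were added after the data had been seen: leaving out _f_at probe sets as well, leaving out of the chaperonin substrates the genes that another list holds, and ranking a list's median among 2927 rotations. A rotation moves the positions of all genes of a list together round the order of measured genes on the chromosome, which keeps neighbours together but does not match on signal. In a simulation of 200 unchanged lists, each of 3 runs of 4 neighbouring genes that share part of their differences, 28 lists fell outside the middle 95% of matched random lists and 9 outside that of rotations.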

Results

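Transcript levels were compared between chaperonin-deleted E. coli cells that had been switched by arabinose to wild type human Hsp60 with Hsp10 and cells switched to the Val98Ile mutant of Hsp60 with Hsp10. The data comprised 1 array of RNA pooled from 2 wild type cultures and 1 array of RNA pooled from 3 mutant cultures. Median signals were 40.4 on the wild type array and 39.1 on the mutant array, and the brightest probe sets reached 10708 and 12053. Of 4225 genes, 2928 were measured, 2551 of them above the floor on both arrays and 377 on 1 array only. There were no replicates, so every difference below compares these 2 pooled samples and carries no error between cultures.

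The host's own chaperonin genes were checked first. groL (b4143, encoding GroEL) gave a signal of 22.5 on the wild type array and 16.9 on the mutant array, at the 37.0th and 32.5th percentiles of all probe sets. groS (b4142, encoding GroES) gave 22.2 and 2.66. Both genes were below the floor of 41.5 on both arrays, where no fold can be given. Whether their probes lie inside the deleted part is not given in the sources used here. No probe set is named for the human genes, so the level of either Hsp60 was not measured.

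The comparison asks which host transcripts differ when the arabinose-inducible operon carries the mutant in place of wild type Hsp60. The first plasmid carried wild type Hsp60 in both groups, and how much of it remained after the switch was not measured. On the mutant array, 188 of 2928 measured genes were at least 2-fold higher and 155 at least 2-fold lower, while 2585 (88.3%) differed by less than 2-fold. Which direction held more genes depended on the setting: the numbers higher and lower were 166 and 200 without centring, 171 and 179 after quantile normalization, 244 and 280 with the floor at the 25th percentile and 290 and 498 with no floor. At least 4-fold, 30 were higher and 9 lower. Of these 2-fold differences, 26 of the higher and 12 of the lower were lower bounds. Signals of the genes measured on both arrays correlated at r = 0.92 across genes, which are not independent replicates. Neighbouring genes differed together: over 828 pairs of genes at most 50 bp apart in the reference, the differences correlated at r = 0.68 across pairs, against at most 0.11 in 1000 random pairings.

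The 12 highest differences among genes above the floor on both arrays began with phoE. phoE (b0241), an outer membrane porin made under phosphate limitation, was 15.3-fold higher on the mutant array, with signals of 87.9 and 1266. phoA (alkaline phosphatase) was 6.03-fold and psiF 5.38-fold higher. srlA, a component of the sorbitol phosphotransferase system, was 10.5-fold higher (3.39 on the log2 scale) and araF, the periplasmic arabinose binding protein, 10.5-fold. metF, metA and metE of methionine synthesis were 9.02-fold, 6.85-fold and 5.56-fold higher. The remaining genes of the 12 highest were bsmA (9.10-fold), ychH (9.08-fold), ybhQ (7.92-fold) and the serine tRNA gene serT (5.51-fold). ychH is read by a probe set of the kind that can match a sequence family, and serT can share signal with other tRNA genes. Among genes above the floor on the mutant array only, tnaC, the leader peptide gene of the tryptophanase operon, was at least 9.26-fold higher. mmuM was at least 7.14-fold, phnI at least 6.93-fold, fcl at least 4.01-fold and phnK at least 3.77-fold higher.

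The 12 lowest differences among such genes began with asr. asr (b1597, acid shock RNA) was 9.39-fold lower on the mutant array, with signals of 2686 and 269. glnA (glutamine synthetase) was 6.30-fold lower, cysE (serine acetyltransferase of cysteine synthesis) 4.67-fold, cysP (a sulfate and thiosulfate binding protein) 4.66-fold and grxA (glutaredoxin) 4.65-fold. yzcX was 5.38-fold, yjcB 5.36-fold, hha 4.53-fold and aroL 3.90-fold lower. The acid resistance regulator gadX was 3.75-fold, the acid chaperone gene hdeA 3.62-fold and hemL 3.59-fold lower. Of the genes above the floor on the wild type array only, tomB, which neighbours hha, was at least 5.33-fold lower. ymgA was at least 3.33-fold, bfd at least 2.58-fold, ykiA at least 2.56-fold and sufC at least 2.31-fold lower. Several of these differences rest on a signal near the floor. With the floor at the 75th percentile of signals, serT, fcl and phnK among the higher genes, and glnA, yzcX, gadX, hdeA, hemL and tomB among the lower ones, differed by less than 2-fold. ymgA, bfd, ykiA and sufC were below that floor on both arrays. srlA, with a wild type signal of 45.4, differed by 1.74 on the log2 scale there and by 2.58 with a pseudocount, and ybhQ, with one of 51.1, by 1.51 and 2.27 against 2.99. phoE and araF differed by 3.24 and 2.65 with the floor at the 75th percentile, against 3.94 and 3.39. With the floor at the 95th percentile of foreign probe sets bfd, ykiA and sufC were under 2-fold.

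**Figure D1:**
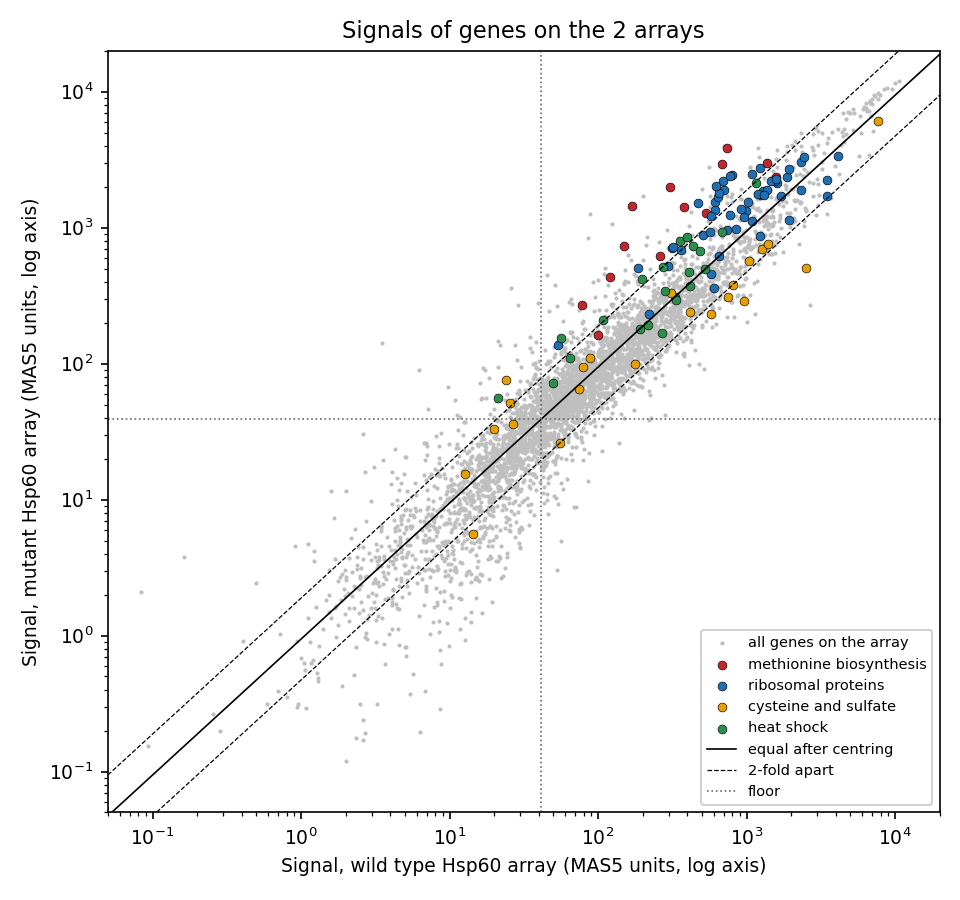
Signal of each gene on the wild type array (horizontal, MAS5 units, log axis) against the mutant array (vertical, MAS5 units, log axis), with 4 gene lists coloured, dashed lines at 2-fold and dotted lines at the floor of 41.5 (scaled signal). The 13 methionine genes all lie above the line of equal signal, and 11 of them beyond 2-fold.

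Methionine synthesis had the highest median of the 24 lists with at least 3 measured genes. All 13 measured genes were higher on the mutant array, 11 of them at least 2-fold, and the median difference was 1.95 on the log2 scale (3.87-fold), with quartiles of 1.33 and 2.39. None of 10000 matched random lists had a median as high, and their middle 95% ended at 0.39. metF (methylenetetrahydrofolate reductase) had signals of 169.3 and 1438, metA (homoserine succinyltransferase, the first step of the pathway) 306.4 and 1977, and metE (cobalamin-independent methionine synthase) 740.2 and 3874. metB and metC, the transsulfuration steps, were 2.39 and 1.33 higher on the log2 scale, metL 1.95, and metN and metI of the methionine transporter 2.21 and 2.01. The third transporter gene, metQ, was 2.30-fold higher. The regulator genes metR and metJ were 1.88 and 1.33 higher on the log2 scale. The smallest differences were in metH, the cobalamin-dependent synthase (0.77), and metK, which makes S-adenosylmethionine (0.66).

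**Figure D2:**
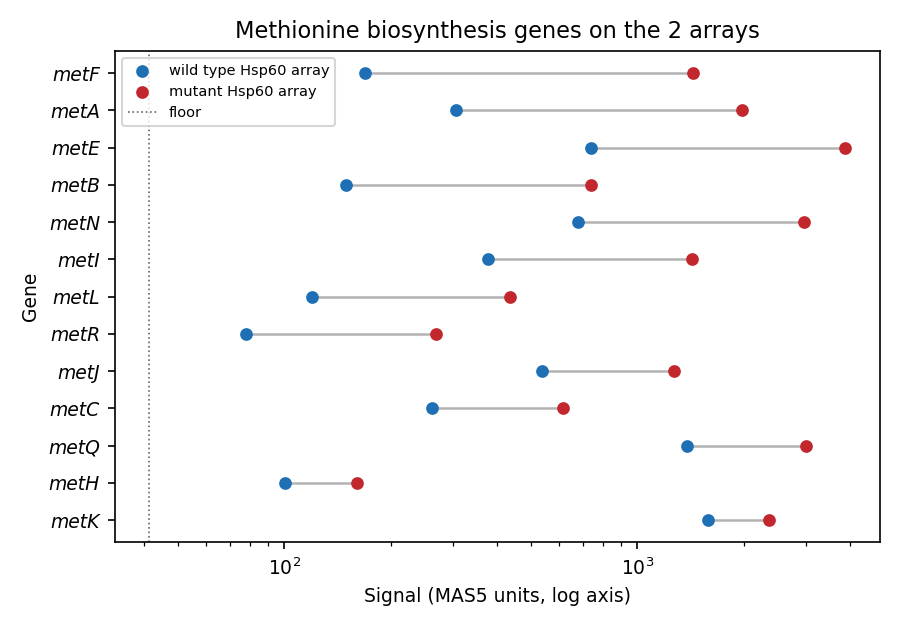
Signals of the 13 methionine biosynthesis genes (vertical axis) on the wild type array (blue points) and the mutant array (red points), in MAS5 units on a log axis, as deposited, with a dotted line at the floor. The mutant signal is the higher one for each gene, from metK (1587 and 2365) to metF (169.3 and 1438).

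Genes of cysteine synthesis and sulfate assimilation differed in the opposite direction. Of 18 measured genes, 5 were at least 2-fold lower on the mutant array and 0 higher, and the median was -0.74. None of 10000 random lists had a median as low. The 5 were cysP, cysA, cysW and cysU, which encode the sulfate and thiosulfate importer, and cysD, a subunit of sulfate adenylyltransferase. cysP and cysA differed by -2.22 and -1.66, and cysE was not among the 18. The highest members were of sulfonate use, ssuC with a bound of 0.95 and tauC with 0.42. The other amino acid pathways (tryptophan, histidine, branched chain, arginine and threonine) had a median of -0.20, inside the random range, but below it with the floor at the 75th percentile (-0.42) or at the 95th percentile of foreign probe sets (-0.35). There 3 of 32 genes, namely ilvE (-1.25), hisC (-1.10) and hisD (-1.06), were at least 2-fold lower and 0 higher; ilvA (0.87) and ilvB (0.54) were the highest. Purine and pyrimidine synthesis had a median of 0.015 over 13 genes, which was below 0 without centring and after quantile normalization, and lay inside the random range. There pyrI was at least 2.38-fold higher, pyrB 0.52 higher on the log2 scale, purC 2.06-fold lower and purE had a bound of -0.76.

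Cytoplasmic heat shock genes were higher on the mutant array. Of 21 measured genes, 5 were at least 2-fold higher and 0 lower, and the median was 0.55 (1.47-fold), a value reached by 1 of 10000 random lists. The 5 were htpG (Hsp90 chaperone, 2.90-fold), clpB (disaggregase, 2.39-fold), lon (protease, 2.28-fold), grpE (nucleotide exchange factor of DnaK, 2.27-fold) and hslR (difference 1.06). dnaK, the Hsp70 chaperone, was 1.97-fold and its partner dnaJ 1.80-fold higher. The small heat shock proteins did not share this direction: ibpB differed by -0.58 and ibpA by -0.10. rpoH, the gene of the heat shock sigma factor, differed by -0.36. The difference of htpG rests on a dim wild type signal of 56.5 and shrinks to 0.21 on the log2 scale with the floor at the 75th percentile.

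Other folding factors and envelope stress genes showed no common direction. The other chaperones had a median of -0.065 over 16 genes, with the trigger factor gene tig 2.38-fold and fkpA 1.80-fold higher, and hdeA 3.62-fold and the iron-sulfur cluster co-chaperone gene hscB 2.71-fold lower. The sigma E list had a median of 0.12 over 15 genes, none of them 2-fold different; fkpA (0.85) and degP (0.58) were its highest members and rseC (-0.37) and rpoH (-0.36) its lowest. The Cpx list had a median of -0.024 over 13 genes, from cpxR (-0.97) and ppiA (-0.89) to yebE (0.86) and degP (0.58). The phage shock list had a median of -0.10 over 6 genes, with pspE (0.77) and pspD (0.44) the highest, and pspA (-0.27) and pspG (a bound of -0.74) the lowest. All 4 medians lay inside the random range, and those of the Cpx and phage shock lists were above 0 after loess and with the floor at the 75th percentile, respectively.

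Genes of proteins described as GroE dependent had a median of 0.29 over 22 measured genes, and 176 of 10000 random lists had one as high. There 3 were at least 2-fold higher and 0 lower: metF, gatD (galactitol dehydrogenase, 3.27-fold) and lldD (lactate dehydrogenase, 1.46 on the log2 scale). The lowest were asd (-0.88) and argE (-0.45). Several members, such as metF, metK, gatD and gatY, also stand in other lists, and the 14 measured genes that do not had a median of 0.23, inside the random range. The median of the list also lay inside that range with the floor at the 75th percentile (18 genes measured), at the 95th percentile of foreign probe sets (21) and with no floor (23).

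Arabinose genes, whose inducer both groups received, were higher on the mutant array. Their median was 0.98 over 9 genes (0.64 after quantile normalization), reached by 10 of 10000 random lists, with 4 genes at least 2-fold higher. These were araF (10.5-fold), araE (the proton symporter, 3.22-fold), araG and araH. The catabolic genes araB, araA and araD, already among the bright genes, were 1.97-fold, 1.66-fold and 1.84-fold higher, with wild type signals of 2902, 4456 and 2135. araC, the regulator gene, was 1.22-fold higher and araJ differed by -0.25. Of the lactose genes, only lacI was above the floor (5913 and 4990, a difference of -0.16), and lacZ, lacY and lacA were below it on both arrays. The difference of lacI depended on the scaling, at -0.49 after quantile normalization and -0.50 after loess. Its signals were above the 95th percentile of all probe sets on each array (1004 and 1047). The array cannot tell a plasmid copy of lacI or araC, if the plasmids carry one, from that of the host. The values of these 2 genes may thus not be of host transcripts alone.

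Uptake and use of other carbon sources had a median of 0.33 over 37 genes, reached by 1 of 10000 random lists, with 10 genes at least 2-fold higher and 0 lower. This median depended on the floor, at 0.24 over 49 genes with the floor at the 25th percentile and 1.18 over 14 genes with it at the 75th. Galactitol genes made up 5 of the 10 (gatA, gatB, gatC, gatD and gatZ), and the others were srlA, dctA (C4-dicarboxylate uptake, 3.49-fold), rbsD, treB and mglB. The other sorbitol genes of the list did not follow srlA: srlB and srlD had bounds of 0.22 and 0.54, and srlE was below the floor on both arrays. tnaA had a bound of 0.33, against a bound of 3.21 for tnaC. The lowest were bounds for glpQ (-0.84) and malF (-0.49). The TCA cycle had a median of 0.81 over 15 genes, reached by 1 of 10000 random lists, and 6 were at least 2-fold higher. All 6 belong to the sdh and suc genes (succinate dehydrogenase, 2-oxoglutarate dehydrogenase and succinyl-CoA synthetase), with sdhA 4.11-fold and sdhB 3.66-fold higher, while fumC (-0.67) and acnB (-0.37) were lower. ATP synthase and aerobic respiration had a median of 0.16 over 28 genes, none 2-fold different and inside the random range. There the cytochrome bo oxidase genes cyoC and cyoD were 1.94-fold and 1.89-fold higher and the cytochrome bd oxidase genes cydB and cydA 1.68-fold and 1.62-fold lower. Anaerobic respiration and fermentation had a median of 0.20 over 24 genes, inside the random range but above it when random lists were not matched on signal, from hybB (2.77-fold lower) and hybA (1.77-fold lower) to pflB (1.87-fold higher) and the formate channel gene focA (2.18-fold higher).

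Ribosomal protein genes were higher and general stress genes lower on the mutant array. Of 54 ribosomal protein genes, 18 were at least 2-fold higher and 0 lower, and the median was 0.62 (1.53-fold); none of 10000 random lists had one as high. rpsC (3.45-fold) and rplW (3.41-fold) were the highest, while rpsM (1.92-fold lower) and rpsD (1.60-fold lower) were the lowest. Of the 54, 45 were higher and 9 lower, and neighbours went together. rpsC, rplV, rpsS, rplB and rplW differed by 1.79, 1.70, 1.72, 1.75 and 1.77, and rpsM, rpsK, rpsD and rplQ by -0.94, -0.55, -0.68 and -0.44. The median of the ribosomal protein genes was 0.40 after quantile normalization. RpoS-dependent genes had a median of -0.48 over 22 genes, a value as low as that of 21 of 10000 random lists, with 4 at least 2-fold lower and 0 higher. The 4 were wrbA (3.11-fold), talA (2.33-fold), dps and treA; osmB (0.71) and bolA (a bound of 0.66) lay in the other direction. The acid resistance list had a median of -0.67 over 7 genes, as low as in 16 of 10000 random lists, and 4 of the 7 values were bounds. Its members gadA, gadB and gadE were below the floor on both arrays and do not enter this value. The median was -1.37, -1.65 and -1.502 with the floor at the 25th percentile, at the 95th percentile of foreign probe sets and with no floor. It lay inside the middle 95% when the positions of the genes were moved together round the gene order (percentile 3.35). gadX, hdeA and gadW were at least 2-fold lower, and mdtE had a bound of 0.070.

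Colanic acid genes, of a capsular polysaccharide, had a median of 1.15 over 9 measured genes, all 9 higher on the mutant array and 5 at least 2-fold. None of 10000 random lists had a median as high, but 41 of 2927 rotations of the gene order did (percentile 98.6). The values of wza, wzb, wzc and fcl were bounds. fcl was at least 4.01-fold and gmd 3.48-fold higher. Only 3 genes were measured with the floor at the 75th percentile, where the median was 0.23 and lay inside the random range.

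The remaining lists with at least 3 measured genes had medians inside the random range. Flagella and chemotaxis had a median of 0.011 over 27 genes, which was below 0 without centring and after quantile normalization; the flagellar master regulator genes flhD and flhC were 2.45-fold and 2.04-fold higher, and flgM and fliT 2.01-fold and 1.75-fold lower. flhC was under 2-fold without centring and after quantile normalization, and flgM after loess. With the floor at the 75th percentile flhD, flhC and flgM differed by 0.22, 0.11 and -0.16, and all 3 were under 2-fold with a pseudocount. The SOS response had a median of -0.30 over 16 genes, from ruvB (2.04-fold lower) and recA (1.84-fold lower) to dinG (0.28) and uvrD (0.43). Oxidative stress genes had a median of -0.29 over 22 genes, with 5 at least 2-fold lower, which were grxA, the thioredoxin gene trxC (2.49-fold), sufA, sufB and sufC, and with hemH (0.59) and ahpF (0.54) the highest. Iron acquisition had a median of -0.11 over 17 genes, with bfd and fhuF at least 2.58-fold and 2.26-fold lower, and bounds of 0.97 for entB and 0.57 for fes. Cold shock genes had a median of 0.46 over 7 genes, with pnp (0.81) and rbfA (0.46) the highest and deaD (-0.23) the lowest. Of type 1 fimbriae only fimA was above the floor (difference 0.57), and none of 7 curli genes was.

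The 2-fold counts of lists depended on the setting too, and higher floors lowered some of them. Methionine (11 higher), the TCA cycle (6 higher) and cysteine and sulfate (5 lower) kept theirs with the floor at the 75th percentile. With the floor at the 75th percentile, 3 heat shock genes were at least 2-fold higher (without htpG and hslR), 2 arabinose genes (without araG and araH), 9 carbon source genes (without mglB), 17 ribosomal protein genes (without rplI) and 1 colanic acid gene (gmd). At that floor 2 RpoS-dependent genes (without talA and treA), 2 other chaperones (without hdeA), 1 oxidative stress gene (grxA), 1 amino acid gene (ilvE), 0 iron acquisition genes and 0 acid resistance genes were at least 2-fold lower. hybB (-0.48), trxC (-0.49), gadW (-0.29), hisC and hisD were then under 2-fold, and ruvB, sufA, sufB, sufC, fhuF, bfd and pyrI were below the floor on both arrays. With the floor at the 95th percentile of foreign probe sets, treA, wzc, ruvB, sufB, sufC, fhuF, bfd and pyrI were under 2-fold. With a pseudocount, hslR, araH, mglB, talA, treA, ruvB, trxC (-0.99), sufA, sufB, sufC, fhuF, bfd, cysD, hisC, hisD, purC and pyrI were, as well as wzc (0.77), wcaA (0.80), wcaK (0.77), rplI and rplS, which left 2 colanic acid genes and 16 ribosomal protein genes at least 2-fold higher.

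Lower floors raised some of the counts, through genes with at least 1 signal below the main floor. Acid resistance had 8 of 11 genes at least 2-fold lower with the floor at the 25th percentile and 10 of 13 with no floor, and colanic acid had 8 of 14 and 9 of 14 higher. Iron acquisition had 3 genes higher and 3 lower of 28 with the floor at the 25th percentile, and 3 higher and 6 lower of 33 with none. In the same 2 settings, carbon sources had 13 higher and 0 lower, then 15 and 2, cysteine and sulfate 2 higher and 6 lower, then 2 and 7, flagella and chemotaxis 2 and 2, then 2 and 5, and purine and pyrimidine synthesis 1 and 3, then 1 and 4. At least 2-fold lower were also 1 and then 4 curli genes, and 1 and then 2 cold shock genes. In both settings fxsA of the heat shock list, nanA of the chaperonin substrates, fdnI of anaerobic respiration and argC of amino acid synthesis were at least 2-fold higher, and hdeB of the other chaperones, blc of the RpoS-dependent genes and hyaA of anaerobic respiration lower. lacA and groS were lower with no floor.

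Scaling changed the counts in both directions. Without centring, hslR (0.97), flhC (0.94) and rplS (0.94) were under 2-fold, while cpxR, ilvM, exbB and exbD were at least 2-fold lower, which gave 4 iron acquisition genes lower and 0 higher. After quantile normalization, gatA, gatZ, sucC, metQ, flhC, rplS (0.98) and rpsJ (0.99) were under 2-fold, while hslU was at least 2-fold higher and hybA and cydB lower. After loess, gatA, gatZ and flgM were under 2-fold, while hslU and aldA were at least 2-fold higher and hybA lower. Heat shock thus had 4 genes higher without centring and 6 after each of the other 2 scalings, and ribosomal proteins 17, 16 and 18 higher, with 1 (rpsM) lower in all 3.

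**Figure D3:**
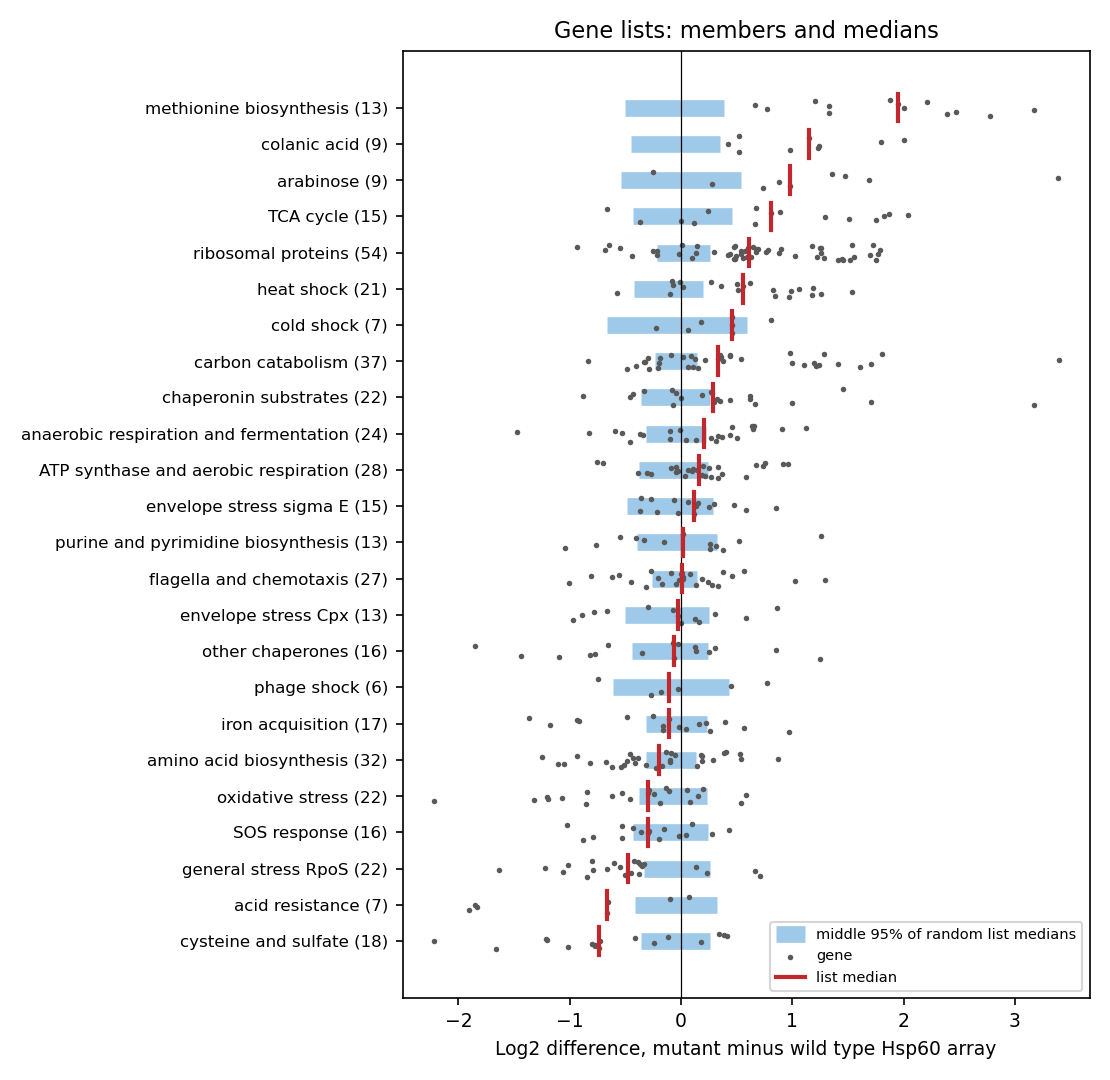
Log2 difference (mutant minus wild type array, horizontal axis) of each measured gene (grey points, bounds included) in the 24 lists with at least 3 measured genes (their number in brackets), with the list median (red) and the middle 95% of the medians of 10000 matched random lists (blue). Medians lie above the blue range in 8 lists and below it in 3, but the blue range treats neighbouring genes as independent, which they were not.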

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

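The test of genomic DNA in this part was chosen after its result was seen; the test of signal strength was not.

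Of 2792 intergenic probe sets without a reference gene, which the comparisons of genes leave out, 876 were above the floor, and 100 were at least 2-fold higher on the mutant array against 15 lower (11.4% and 1.71% of those measured). The numbers were 83 and 20 without centring and 94 and 17 after quantile normalization. A trend with signal strength does not account for this, since 99 were higher and 15 lower after the loess fit. Genomic DNA carried over into the mutant sample is not excluded. Of probe sets below the floor on the wild type array, the 1530 named by locus had a median difference of -0.15 (95% bootstrap interval -0.20 to -0.095). The 2044 intergenic ones had 0.13 (0.096 to 0.16). These intervals treat probe sets as independent and carry no error between arrays or cultures. Choosing probe sets by a low wild type signal alone also favours higher mutant values. The 2 kinds differ in sign, and dim probe sets do not decide. Transcripts that extend from neighbouring genes into these regions, or unannotated small RNAs, were not tested and remain open, as does the difference between the cultures.

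The intergenic probe set with the highest difference, whose name gives positions 1983093 to 1983161 on the reverse strand in an unstated build, had signals of 31.1 on the wild type and 1583 on the mutant array. The beta-lactamase probe set of plasmid pBR322, outside the comparisons of genes, had signals of 5871 and 7568, a 1.37-fold difference in cells kept under ampicillin.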

How the results depend on the processing

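No sign changed among named genes or the 11 lists outside the random range. For a single gene, a floor or a pseudocount cannot change the sign. Each named gene has 1 probe set, so averaging probe sets or leaving some out cannot change it either. For named genes only the scalings (no centring, quantile normalization and loess) could have. Values of the 11 lists moved by less than their spread in 105 of 122 cases, and values of named genes in 1171 of 1282. The spread is the SD of random list medians for lists, and 0.31 (between probe sets of a gene) for genes. Part of the 1171 could not have moved further. Averaging or leaving out probe sets returns the same value for a named gene that keeps its probe set. Leaving out the centring shifts all genes above the floor on both arrays by 1 common amount, which is smaller than 0.31. The count of 1171 thus overstates how far the named genes were tested. Genes at least 2-fold higher and lower numbered 188 and 155 in the main setting, 115 and 76 with the floor at the 75th percentile, 290 and 498 with no floor, 244 and 280 with the floor at the 25th percentile, and 135 and 83 with a pseudocount. Without centring they numbered 166 and 200, and after quantile normalization 171 and 179. Other list medians that moved were, with the floor at the 75th percentile, methionine 1.71, carbon catabolism 1.18, general stress -0.66 and colanic acid 0.23; at the 25th percentile, acid resistance -1.37, carbon catabolism 0.24 and cysteine and sulfate -0.49; at the 95th percentile of foreign probe sets, acid resistance -1.65 and colanic acid 0.81; with no floor, acid resistance -1.502 and carbon catabolism 0.24; with a pseudocount, methionine 1.65 and colanic acid 0.77. Quantile normalization gave arabinose 0.64 and ribosomal proteins 0.40, and loess 0.69 and 0.45. Colanic acid came inside the random range with the floor at the 75th percentile. Among rotations of the gene order, chosen after seeing the data, 8 of 24 lists lay above and 2 below the middle 95%, and acid resistance came inside (percentile 3.35). The chaperonin substrates came inside it with the floor at the 75th percentile, at the 95th percentile of foreign probe sets and with no floor, and also when members shared with other lists were left out (0.23), also chosen after seeing the data. The cause of these moves was not tested. No paired analysis was possible because each group is 1 array, and for the same reason no replicate could be left out. Of the 13 lists inside the range, amino acids came below it with the floor at the 75th percentile (-0.42) and at the 95th percentile of foreign probe sets (-0.35), and anaerobic respiration came above it with unmatched random lists. Signal over background limits dim genes, since 1297 of 4225 were below the floor on both arrays and 377 gave only a bound.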

Other observations

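Of the tests in this part, those of amino acid synthesis and of growth state, the ranks of tRNA and rRNA genes and all ranks among rotations of the gene order were chosen after the results were seen. The gene lists named here were set after the data had been looked at, except that the values of 13 phosphate genes had not been.

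Beyond the lists fixed in advance, more genes of methionine supply were higher on the mutant array. mmuP and mmuM, which take up S-methylmethionine and convert it to methionine, differed by 2.22 and a bound of 2.84 on the log2 scale, ybdL (a methionine aminotransferase) by 2.27 and its neighbour hcxA by 2.07. Genes for tRNA differed as well: 47 of 49 measured were higher, 15 of them at least 2-fold. Their median was 0.72, which none of 10000 random lists reached, although near-identical tRNA genes share signal. All 16 rRNA genes, which are near-identical copies of one another within each kind, were higher by 0.22 to 0.47, inside the range of random lists matched on brightness (percentile 78.8) but above that of rotations of the gene order, which are not matched (98.3). Genes of glutamine and nitrogen supply were lower: the 8 measured of 10 had a median of -1.03, with glnA at -2.66, the glutamine transporter genes glnH and glnP at -0.91 and -1.27 and the regulator genes glnL and glnG at -1.01 and -1.06. Of 4 ribosome hibernation genes, rmf (-0.86), hpf (-0.77) and sra (-0.66) were lower and raiA (1.77) higher.

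The higher methionine genes had the highest median of the 24 lists fixed in advance, and none of 2927 rotations of the gene order reached it. A trend with signal strength does not account for it, since the median was 1.96 after the loess fit. The other amino acid pathways did not share this direction: their median was -0.20, inside the range of random lists in the main setting. It lay below 0.5 by more than the SD of random lists (0.12). That level of 0.5 was set after the median was known, so passing it adds nothing to this contrast. A different growth state of the pooled cultures at harvest cannot be told apart from the mutation: general stress genes differed too (median -0.48), and each group is 1 pooled sample. The mutant chaperonin itself remains open as an untested explanation.

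Phosphate starvation genes were the second such pattern: phoA, phoE, psiF and 13 measured phn genes (phosphonate use) had a median of 1.89, with 14 of 16 at least 2-fold higher. Another 13 PhoB-regulated genes, listed before their values were looked at to test whether the response differed as a whole, had a median of 0.53, with 11 of 13 higher, 3 of them at least 2-fold (ugpA, ugpB and ugpE), and it was 0.52 after the loess fit, which argues against a trend with signal strength. Most of the 13 lie in operons, and random lists of single genes make such a median look too unusual (percentile 99.8); among rotations of the gene order it lay at percentile 98.6, and at 98.4 after the loess fit. The response may thus differ as a whole but unevenly, since pstS, the phosphate binding protein gene, was already bright (3319 and 3511) and differed by 0.17, and phoH by -0.83. Whether phosphate in the medium, growth or the mutant chaperonin lies behind it was not tested.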
